A study of Saccharomyces cerevisiae with 36 samples.

How the data were processed

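Yeast carrying barcoded pairs of fusion proteins was sampled before selection (medium with histidine) and after growth without histidine, and barcode pairs were counted by sequencing, in 36 libraries of 13 library sets. The deposited files hold read counts per ordered pair of proteins as square matrices, and per the submitters' processing notes counts before and after selection were compared with DESeq2, whose version, like the read alignment and barcode matching, was not given in the sources used here. Only the counts were used here, and all log2 changes and tests were computed anew. Biological replicates are those of the labels in the NCIP, Coiled and DHD pools. For the NCIP library of replicate 2 at 10 mM the number comes from its library set, since its title gives none. The labels of the Bcl pool give none, and its 2 library sets were taken as replicates. The outgrowth libraries all belong to biological replicate 1 of the NCIP pool, and the Coiled pool had technical runs of each library, which were summed.

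Samples were grouped by assay, selection state, 3-AT concentration and outgrowth time as titles and descriptions give them. In 4 libraries title and description gave opposite selection states, and these entered no comparison. Each barcode map held 1 barcode per protein, so an analysis by barcode was not run, and across all maps 76 of 459 barcodes stood for more than 1 protein name. In the Bcl pool only the 225 ordered pairs of proteins that both library sets hold were tested.

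Counts of each comparison were fitted in R 4.3.3 with edgeR 4.0.16 (glmQLFit with robust estimation, glmQLFTest, limma 3.58.1), with TMM factors and Benjamini-Hochberg adjusted p under 0.05, on pairs with a total of at least 10 reads per library. Both NCIP selections were fitted together. A comparison has 2 replicates per group. SE is the absolute log2 change divided by the square root of the F statistic of its test. It rests on a spread that the fit estimates over many pairs, not on the 2 replicates of a pair alone. Changes in single replicates are log2 ratios of scaled reads. The common dispersion between replicates was 0.523 in the NCIP pool, 0.371 in the Coiled pool, 0.688 in the DHD pool and 0.789 in the Bcl pool.

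Intended pairs were read from protein names: chains A and B of 1 design, an odd-numbered peptide with the next even number of its series, any AN with any BN peptide, and an inhibitor with the homologue in its name. The difference of medians between intended pairs and other heterodimers was tested by permuting partner names, 10000 times or exactly where 6 or fewer pairs of names exist. Pools with 1 library per condition were described by log2 ratios with a pseudocount of 1 read for pairs with at least 10 reads before selection, with 95% intervals from 200 resamplings of the reads. Correlations and permutations were computed in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots were drawn with matplotlib 3.10.9.

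Groups, tests, thresholds, intended pairs and the rule for naming pairs were set before the data were examined. The rule names, per comparison, up to 10 intended and 10 other pairs with the largest change past the threshold and above 0 in each replicate, the 5 lowest intended pairs, AN with BN pairs, inhibitors with their homologues, and up to 3 proteins per side with the highest median over partners. Lists chosen later were the intended DHD pairs by their lower replicate, inhibitors against every homologue, PUMA variants with MCL1, forms of 1 parent design, and equal numbers across peptide series.

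Same-numbered libraries of a comparison come from the same library set per the labels, so the numbers pair them. The main fits left this pairing out, and replicate as a block was an alternative. Deviations from group means correlated between same-numbered libraries with 0.326 in the DHD pool, 0.804 in the Bcl pool, 0.162 and 0.143 in the NCIP pool at 2 mM and 10 mM, 0.791 for 10 mM over 2 mM, and 0.260 in the Coiled pool.

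Alternatives were DESeq2 1.42.0, library size without TMM, no filter, a filter at 50 reads per library, replicate as a block, each library left out, the first technical run alone, the outgrowth libraries summed, other pseudocounts, and, chosen later, forms of 1 parent left out, the mean over all R forms in place of the plain 2H form, and medians of row and column proteins subtracted.

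The fits were tested on simulated data with the common dispersion and library sizes of each pool and means from the reads before selection. Raised pairs were drawn from those with at least 10 expected reads in the smallest library. The recovery therefore does not cover pairs with fewer reads or with a spread unlike the common one. Of pairs raised by a log2 of 4 the fit recovered 2% in the DHD pool, 0% in the Bcl pool, 60% in the NCIP pool and 68% in the Coiled pool, and of those changed by 8 it recovered 75%, 100%, 100% and 100%. False calls numbered 4, 1, 1 and 1, with 200 changed pairs simulated in the DHD and Coiled pools and 10 in the others. In 400 simulated matrices of 30 designs without a difference the permutation gave p under 0.05 in 22, and with a log2 difference of 1 in 399.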

Results

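Interactions between synthetic and natural proteins were measured in yeast with a 2-hybrid growth selection read out by sequencing. Each yeast cell carried a pair of fusion proteins with their barcodes, and cells whose pair interacted made more of the HIS3 product, an enzyme of histidine synthesis. Barcode pairs were counted before selection, in medium with histidine, and after growth without histidine, in most assays with 3-AT, a competitive inhibitor of the HIS3 product. Each library was a matrix of read counts over ordered protein pairs, in which a row protein met a column protein. Which of these axes was the DNA-binding fusion was not given in the sources used here, so pairs are written as row protein with column protein.

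The 36 libraries came from 13 library sets. The 4 pools compared with replicates were the NCIP pool of 12 coiled-coil peptides, the Coiled pool of 18769 ordered pairs (coiled-coil peptides, larger 2-chain designs, and PUMA and Bcl-2 family proteins with inhibitors), the DHD pool of 337 proteins (designed heterodimers, with Bcl-2 family proteins and their inhibitors) and the Bcl pool of 15 shared proteins (6 Bcl-2 family homologues and 9 designed inhibitors). Each had 2 replicates before and 2 after selection, named as biological replicates in the labels except in the Bcl pool, where the labels give no replicate and its 2 library sets were taken as replicates 1 and 2. In the Coiled pool each replicate had 2 technical runs, which were summed, and the NCIP pool had selections at 2 mM and at 10 mM 3-AT. The 3-AT concentrations used here are those of the sample descriptions (1 mM in the other pools, none in the libraries without a group), while the growth protocol common to all samples gives 3 mM. Another 4 pools had 1 library per condition, and 4 libraries had no group because their title and description gave opposite selection states. Homodimer pairs hold the same protein on both sides, and intended pairs hold designed partners as read from their names.

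Depth differed widely between pools. The NCIP libraries of replicates 1 and 2 held 402198 and 370902 reads before selection, 477199 and 327863 at 2 mM and 430111 and 445958 at 10 mM, with a median of 2866 and 2386 reads per pair before selection. With technical runs summed, the Coiled libraries held 22515090 and 14428752 reads before and 16479810 and 17791146 after selection. Bcl-2 family homologues other than MCL1 and inhibitors were nearly absent from them. Before selection in replicate 1 both classes had a median of 1 read per pair as row proteins, and 10 and 19 as column proteins. The other series had medians of 843.5 to 2988 as row proteins. The DHD libraries of replicate 1 held 33394129 reads before and 34925075 after selection, with medians of 228 and 34 reads per pair. Those of replicate 2 held 4057624 and 3959528, with medians of 23 and 3 reads per pair. Over the shared proteins the Bcl libraries held 2564663 and 385898 reads before and 2304920 and 444597 after selection. The pools with 1 library per condition held 21994913 and 20288936 reads before and after selection (DHD subset), 1271971 and 1107694 (NICP and mALb T), 7787601 and 8221378 (AnBn, NICP, N and PA) and 8857819 and 8598079 (mALb R). Reads were PCR products without molecular identifiers, so every interval of a share or of a pool with 1 library per condition covers counting error only.

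A log2 change compares reads after with reads before selection, with library totals scaled by TMM factors, and is relative to the bulk of pairs. With library size alone the median of all pairs moved from -0.21 to -4.50 in the NCIP pool at 2 mM, from -0.14 to -4.81 at 10 mM, from 0.05 to -2.29 in the Coiled pool, from -0.16 to -2.53 in the DHD pool and from -0.27 to -1.81 in the Bcl pool. Pairs share proteins and are not independent replicates. The difference between intended pairs and other heterodimers was therefore tested by permuting which proteins were partners.

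The NCIP assay asked which of 12 coiled-coil peptides, which their names order as 6 pairs, grew together. At 2 mM 3-AT the 12 intended ordered pairs went from 5.43% and 5.21% of reads before selection (replicates 1 and 2; Wilson 95% intervals 5.36 to 5.50 and 5.14 to 5.28) to 87.4% and 85.3% after it (87.3 to 87.5 and 85.2 to 85.4). Intended pairs had a median log2 change of 8.93 and the 120 other heterodimers one of -0.27, a difference of 9.20 (8.11 in replicate 1 and 9.96 in replicate 2; exact permutation p = 0.0056, two-sided, 720 arrangements, smallest possible 0.0028). All 12 intended pairs were above 0 in both replicates. Jerala_P4 with Jerala_P3 rose by 11.17 ± 1.89 (SE, n = 2), Jerala_P2 with Jerala_P1 by 10.71 ± 2.08, Jerala_P1 with Jerala_P2 by 10.70 ± 1.85, Jerala_P10 with Jerala_P9 by 10.64 ± 1.92 and Jerala_P9 with Jerala_P10 by 9.79 ± 1.78. Jerala_P12 with Jerala_P11 rose by 8.97 ± 1.95 and Jerala_P8 with Jerala_P7 by 7.73 ± 1.86. The lowest intended values were 3.44 ± 1.31 for Jerala_P7 with Jerala_P8 and 3.54 ± 1.73 for Jerala_P6 with Jerala_P5, neither past the threshold. The latter rested on replicate 1 (4.61 and 0.29 in replicates 1 and 2). The homodimer of Jerala_P11, named after its value was seen, rose by 3.71 ± 0.69.

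In edgeR's quasi-likelihood test 8 NCIP pairs were enriched at 2 mM, 7 of them intended, and 0 were depleted (16 higher and 1 lower at an unadjusted p under 0.05; DESeq2, 21 enriched and 0 depleted). Adjusted over the list alone, 11 of the 12 intended pairs were enriched. Without the replicate 1 library before selection 0 pairs were enriched, without that of replicate 2 there was 1, and without the replicate 1 library after selection there were 13. With library size in place of TMM 7 pairs were enriched and 92 depleted.

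**Figure D1:**
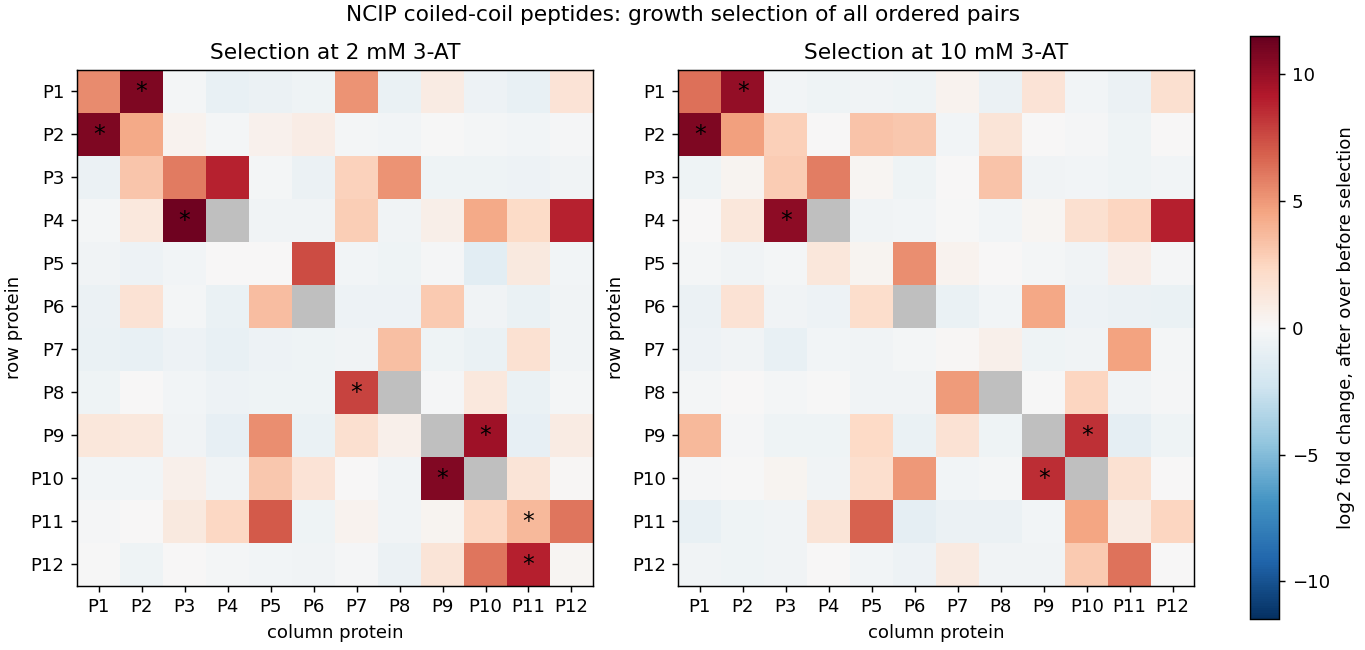
Log2 change of each ordered pair of NCIP peptides after selection at 2 mM (left) and 10 mM 3-AT (right), row protein by column protein, from the fit to 2 replicates; stars mark pairs past the threshold and grey cells pairs with too few reads to test. Dark cells include intended pairs such as P4 with P3 at 11.17 and 10.33 and the other pair P4 with P12 at 8.88 and 8.90, which was not past the threshold and was high in replicate 2 only (-0.06 and 10.46 in replicates 1 and 2 at 2 mM, 0.25 and 10.48 at 10 mM).

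At 10 mM 3-AT the intended NCIP pairs held 83.3% and 74.8% of reads. Their median log2 change was 6.03 against -0.26 for other heterodimers, a difference of 6.29 (exact permutation p = 0.0056), and 11 of 12 were above 0 in both replicates. Jerala_P2 with Jerala_P1 rose by 10.73 ± 2.08, Jerala_P4 with Jerala_P3 by 10.33 ± 1.83, Jerala_P1 with Jerala_P2 by 10.07 ± 1.80, Jerala_P10 with Jerala_P9 by 8.51 ± 1.77 and Jerala_P9 with Jerala_P10 by 8.43 ± 1.69. Jerala_P7 with Jerala_P8 was at 0.60 ± 1.20, Jerala_P6 with Jerala_P5 at 2.05 ± 1.63 (3.02 and -0.13 in replicates 1 and 2) and Jerala_P11 with Jerala_P12 at 2.49 ± 1.71. In edgeR's test these 5 pairs were enriched and 0 pairs depleted (12 higher and 1 lower at an unadjusted p under 0.05; DESeq2, 17 enriched and 0 depleted, with no adjusted p for 102 pairs), and 9 of 12 intended pairs were enriched adjusted over the list alone. Without either library before selection 0 pairs were enriched. With replicate as a block 2 pairs were depleted, and with library size alone 6 were enriched and 97 depleted.

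Set directly against 2 mM, the selection at 10 mM lowered intended pairs relative to the others. Their median log2 difference of 10 mM over 2 mM was -2.17 against 0.10 for other heterodimers, a gap of -2.26 (-0.80 in replicate 1 and -2.47 in replicate 2; exact permutation p = 0.0056). For single pairs 0 changes passed edgeR's test (0 higher and 2 lower at an unadjusted p under 0.05; DESeq2, 2 pairs; with replicate as a block also 0), which does not show that single pairs were unchanged. Among the pairs lower in both replicates, none past the threshold, were the Jerala_P11 homodimer at -2.80 ± 0.72 (-2.97 and -2.54), Jerala_P11 with Jerala_P12 at -3.70 ± 1.80 (-2.97 and -4.32), Jerala_P7 with Jerala_P8 at -2.84 ± 1.28 (-3.19 and -2.07) and Jerala_P8 with Jerala_P7 at -2.81 ± 1.48 (-1.74 and -3.51). These pairs were named after their values were seen. Jerala_P2 with Jerala_P1 was at 0.02 ± 1.38, with replicates on opposite sides of 0 (2.51 and -0.54), as were Jerala_P1 with Jerala_P2 (1.66 and -1.55), Jerala_P4 with Jerala_P3 (0.71 and -1.24) and Jerala_P9 with Jerala_P10 (0.29 and -2.10).

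Without selection the NCIP pool drifted the other way. In biological replicate 1, sampled at 24, 44 and 60 hours of outgrowth with histidine, intended pairs held 5.43%, 4.18% and 3.66% of reads (Wilson 95% intervals 5.36 to 5.50, 4.12 to 4.25 and 3.60 to 3.72). Their median log2 ratio to 24 hours was -0.40 at 44 hours and -0.65 at 60 hours, against -0.01 and -0.05 for the other 120 heterodimers, and the counting interval of 11 of the 12 lay below 0 at each time. There was 1 library per time, so the drift has no replicate check.

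The Coiled pool asked which designed partners found each other in a pool of several design series. Intended pairs had a median log2 change of 3.84 against 0.04 for other heterodimers, a difference of 3.80 (4.34 and 3.31 in replicates 1 and 2; permutation p = 0.0002, the smallest that 10000 permutations allow), and 72 of 113 were above 0 in both replicates. Jerala_P10 with Jerala_P9 rose by 8.45 ± 0.50 (SE, n = 2), Jerala_P4 with Jerala_P3 by 7.81 ± 0.30, IL19_B with IL19_A by 7.58 ± 0.68 and IL19_A with IL19_B by 7.53 ± 0.64. mALb8_A with mALb8_B rose by 7.51 ± 0.81, P6A with P5A by 7.47 ± 0.60, P8A with P7A by 7.46 ± 0.70, P7A with P8A by 7.28 ± 0.66, P5A with P6A by 7.08 ± 0.60 and IL9_B with IL9_A by 7.07 ± 0.62. The lowest intended values, none past the threshold, were -2.22 ± 0.80 for BW10_B with BW10_A, -1.40 ± 0.53 for BN3 with AN3, -0.99 ± 0.52 for IL8_2H_A with IL8_2H_B, -0.91 ± 0.71 for AN3 with BN35 and -0.86 ± 0.36 for BW8_B with BW8_A. Names of mALb R designs are given here without the number that opens them.

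Intended pairs of the Coiled pool are given by series, without a test between series. All 12 intended Jerala_P pairs were above 0 in both replicates, with a median of 6.05, and 7 were enriched (12 adjusted over the list alone; exact permutation p = 0.0028 within the series). Medians were 6.45 for the 6 N pairs, 2 of them enriched (6 adjusted over the list alone), and 7.37 for the 4 PA pairs, all 4 enriched (4 adjusted over the list alone); too few arrangements exist in these series for p under 0.05, with 0.333 and 1 as the smallest. Of 20 mALb T pairs 14 were above 0 in both replicates, with a median of 5.58, and 4 were enriched (13 adjusted over the list alone; permutation p = 0.0002). Of 53 mALb R pairs 26 were above 0 in both replicates, with a median of 0.73, and 6 were enriched (16 adjusted over the list alone; permutation p = 0.068). The 18 AnBn pairs had a median of 2.35, and 3 were enriched (4 adjusted over the list alone, with exact permutation p = 0.2, the smallest possible). Other pairs within the series had medians of -0.26 for Jerala_P, 2.77 for N and 0.74 for PA. Within mALb T, mALb R and AnBn these were 0.30, 0.25 and 1.40.

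In edgeR's test the enriched pairs, out of 15532 tested, were 26 intended pairs, 124 other heterodimers and 1 homodimer (BW5_2Hx12j_B, named after its value was seen), and 0 pairs were depleted (1637 higher and 1449 lower at an unadjusted p under 0.05; DESeq2, 2004 enriched, 65 of them intended, and 348 depleted). Adjusted over the list alone, 58 of the 113 intended pairs were enriched. Without either library before selection 2 pairs were enriched, 1 of them intended; without the library after selection of replicate 1 there were 3711 enriched, 68 of them intended, and 2635 depleted, and without that of replicate 2 there were 3915, 72 and 3270. With library size alone 507 pairs were enriched, 52 of them intended, and 8646 depleted, and with replicate as a block 2 pairs were depleted.

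**Figure D2:**
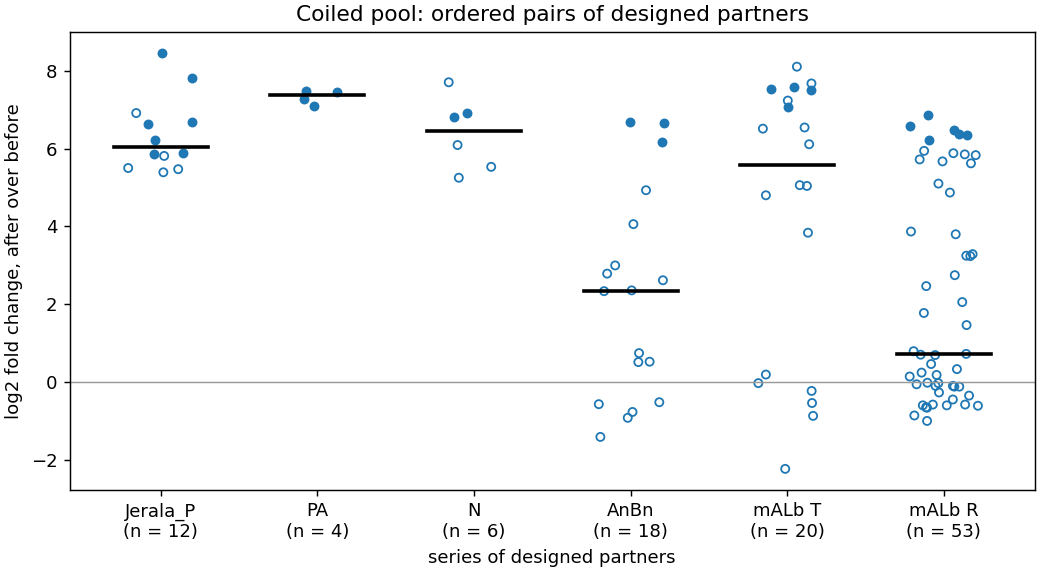
Log2 change after over before selection of each intended ordered pair of the Coiled pool, by series, from the fit to 2 replicates; filled points passed the threshold and bars are medians. The medians lie at 6.05 for Jerala_P, 7.37 for PA, 6.45 for N, 2.35 for AnBn, 5.58 for mALb T and 0.73 for mALb R.

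Among pairs not named as partners, variants of PUMA, a BH3-only protein, rose with MCL1, an anti-apoptotic Bcl-2 family protein that binds BH3 peptides. PUMA_M144A_A139G with MCL1 rose by 8.31 ± 0.32 (SE, n = 2), PUMA_M144A_E132A by 8.16 ± 0.40, PUMA_M144A_E136G by 8.13 ± 0.69, PUMA_M144A_E158A by 8.06 ± 0.39 and PUMA_M144A_Y152A by 8.02 ± 0.51. In this list, made after the names were seen, 10 of 13 variants were enriched with MCL1 as column protein (median 7.74) and 4 of 13 with MCL1 as row protein (median 6.27). PUMA_M144A_L141A lay at -0.11 ± 0.46 and -0.61 ± 0.43 in these orientations, and PUMA_M144A_L148A at 4.32 ± 1.02 and 2.85 ± 0.93, none past the threshold. With all other proteins PUMA variants had medians of -0.23 as row and -0.72 as column proteins, and MCL1 had medians of 0.29 as column and 1.60 as row protein with proteins other than PUMA, with 0 pairs enriched.

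**Figure D3:**
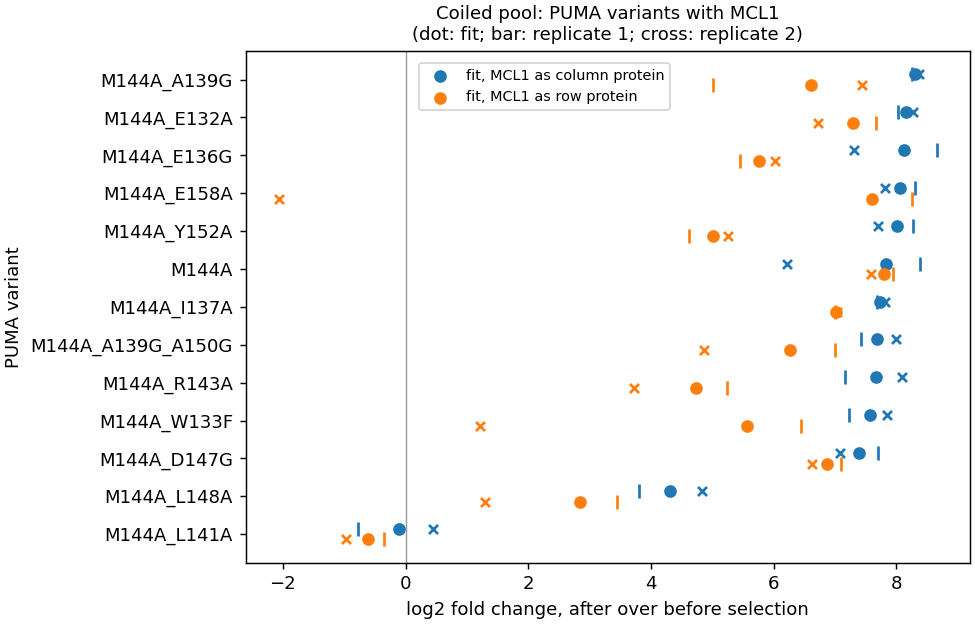
Log2 change after over before selection of PUMA variants with MCL1 in the Coiled pool, with MCL1 as column (blue) or row protein (orange); dots are the fit, bars replicate 1 and crosses replicate 2. Values with MCL1 as column protein reach from -0.11 for M144A_L141A to 8.31 for M144A_A139G.

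The other named pairs outside the design were N2 with mALb8_cutT1_B at 8.23 ± 0.52 and mALb8_cutT1_B with N2 at 8.01 ± 0.81, mALb8_cutT1_A with mALb8_B at 8.17 ± 0.72, mALb8_B with BW3_B at 7.98 ± 0.80, and mALb8_cutT1_B with BW5_2Hx12j_A at 8.15 ± 0.56. The last lay at -1.22 with the fusions swapped, mALb8_B with BW3_B at 3.90 and mALb8_cutT1_A with mALb8_B at 6.66. Several of these proteins had more than 1 of the 124 enriched other heterodimers: N2 6 and mALb8_B 5 as row proteins, and BW5_2Hx12j_A 7 as column protein. Opposite chains of different forms of 1 parent design, such as mALb8 and mALb8_cutT1, had a median of 2.32 over 337 pairs, 23 of them enriched. Unrelated designs within series had a median of 0.19, and pairs between series one of -0.03. The latter class also holds T with R forms of 1 parent, so the 2 classes overlap. Some mALb8 chains were high with most partners, and whether 2.32 goes beyond this was not tested. In the DHD pool such pairs had a median of -0.32 over 234 pairs (0.21 and -1.59 in replicates 1 and 2), against -0.13 within and -0.17 between series.

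The mALb designs occur in forms T and R, whose meaning was not given in the sources used here. For the 6 designs compared, with the plain 2H member taken as the R form, R minus T was -3.43 ± 3.95 on average (SD, n = 6; 95% interval -7.57 to 0.71; exact sign-flip permutation p = 0.0938, two-sided). R was lower in 5 designs, as for BW5 (-0.45 against 5.79) and IL14 (-0.06 against 6.01), and higher in BW8 (2.30 against -0.86, where the R value was 2.86 and 0.40 in replicates 1 and 2 and -0.63 in the mALb R pool). Other R forms ranged from near T values to far below them. BW5_2Hx2 was at 6.12 and BW5_2Hx1 at 1.80 against 5.79 for T. IL9_2Hx2 was at 5.62 (1 orientation) and IL9_2Hx1 at 0.08 against 6.81. IL14_2Hx2 was at -0.27 and IL14_2Hx1 at 0.17 against 6.01. The mALb8 R forms reached from 1.31 to 6.35 against 6.27. With the mean over all R forms and mALb8 included, an alternative chosen after the values were seen, R minus T was -2.56 over 7 designs (exact sign-flip permutation p = 0.0781). Neither test separated the forms.

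In the AnBn peptides the log2 change was set against the numbers in the names, read as peptide length, and the test did not pass. AN4 with BN4 averaged 6.67 over both orientations (6.90 and 6.44 in replicates 1 and 2), AN4 with BN35 5.55, AN35 with BN35 1.87 (-0.15 and 2.72 in replicates 1 and 2) and AN3 with BN3 -0.98. AN4 with BN3 was at 3.42, above AN35 with BN4 at 2.48, an order held by replicate 1 (4.19 and 2.46) but not by replicate 2 (0.53 and 2.27) or the AnBn pool (1.88 and 5.90). Over the 9 combinations the correlation with the summed number was r = 0.877 (Spearman rho 0.846; exact permutation p = 0.056, 36 arrangements, the smallest possible). The 9 values share 6 peptides and are not independent.

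Proteins with a high median over all partners had it mostly on 1 side of the pair. As row protein N1 had a median of 5.35 over 129 partners and was above 0 in both replicates with 122 of them, but its median was -0.07 as column protein. mALb8x12_fdrtc_B followed as row protein with 3.09 (0.81 as column) and mALb8x12j_fdrtc_B with 3.07 (0.93 as column). The highest column proteins were mALb8x12j_rprtc_B at 2.47 (2.33 as row), mALb8x12_rprtc_B at 2.20 and BW5_A at 1.61. Between orientations the correlation was r = 0.298 (Spearman rho 0.192) over all 7089 unordered Coiled pairs and r = 0.880 (rho 0.791) over the 55 intended ones.

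The DHD pool asked which of 337 proteins, mostly designed heterodimers, grew with their designed partner. Intended pairs had a median log2 change of 0.53 against -0.16 for other heterodimers, a difference of 0.69 (0.64 in replicate 1 and 0.45 in replicate 2; permutation p = 0.0002, the smallest that 10000 permutations allow). In both replicates 119 of 325 intended pairs (36.6%) and 20.3% of other pairs were above 0; above a log2 change of 3 these were 52 intended pairs and 1.46% of other pairs. The difference was 2.22 with a filter at 50 reads per library, 1.53 without the replicate 1 library before selection, and 0.42 without the replicate 1 library after it. The filter also counts reads after selection, so pairs scarce before it are kept mainly where they rose. The 2.22 is therefore not independent of the change it measures. By series the difference was 0.54 for the 195 HT_DHD pairs (0.56 and 0.48 in replicates 1 and 2; permutation p = 0.0002), 0.78 for the 70 ZCON pairs (0.83 and 0.13, permutation p = 0.0002), 0.76 for the 42 DHDr2 pairs (0.37 and 0.28, permutation p = 0.004) and 0.30 for the 10 mALb T pairs (0.51 and 0.68, exact permutation p = 0.6). For the 8 inhibitor and homologue pairs it was 6.78 (8.25 and 3.96; exact permutation p = 0.0833, the smallest possible).

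No single DHD pair passed the threshold of edgeR's test, which gave 0 enriched and 0 depleted of 110004 pairs (3832 higher and 3517 lower at an unadjusted p under 0.05), also 0 of the 325 intended pairs adjusted over the list alone (1 of the 42 DHDr2 pairs adjusted over that list alone). DESeq2 gave 7961 enriched pairs, 105 of them intended, and 115 depleted, but no adjusted p for 188 of the 325 intended pairs and 82799 of the 109427 other heterodimers. Without the library after selection of replicate 1 edgeR gave 8347 enriched pairs, 66 of them intended, and 2063 depleted, and without that of replicate 2 it gave 6913, 110 and 508. Log2 ratios of the replicates correlated weakly (Spearman rho 0.216 over all pairs and 0.5 over intended pairs).

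**Figure D4:**
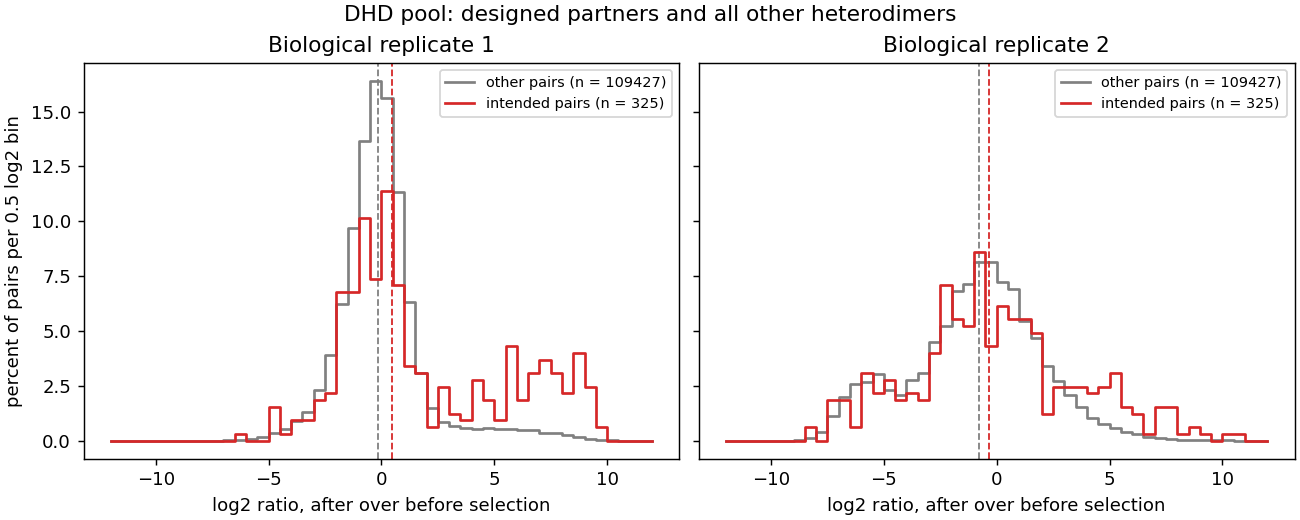
Distribution of log2 ratios after over before selection in the DHD pool for intended pairs (red, n = 325) and other heterodimers (grey, n = 109427), as percent of pairs per bin, by biological replicate; dashed lines are medians. Median differences are 0.64 in replicate 1 and 0.45 in replicate 2.

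Because no DHD pair passed the test, intended pairs are named by the higher value of their lower replicate, a rule set after the calls were seen. mALb8_B with mALb8_A lay at 7.91 and 9.11 in replicates 1 and 2, ZCON_VR_2_cutT2_B with ZCON_VR_2_cutT2_A at 7.63 and 7.95, and B_HT_DHD_90 with A_HT_DHD_90 at 7.94 and 7.58. B_HT_DHD_45 with A_HT_DHD_45 had a fit value of 8.75 ± 4.44. B_HT_DHD_93 with A_HT_DHD_93 lay at 8.83 and 7.24, mALb8_cutT1_A with mALb8_cutT1_B at 7.19 and 7.24, and Bcl-B with alphaBCLB at 8.57 and 7.04. Among the other inhibitor and homologue pairs alphaMCL1 with its target was at 8.99 ± 5.34, alphaBFL1 with Bfl-1 at 7.32 ± 4.59 and alphaBCL2 with Bcl-2 at 6.09 ± 3.48 (7.41 in replicate 1; from 38 reads to 0 in replicate 2), none past the threshold. At the low end 3 intended pairs had 0 reads after selection in both replicates. Against a floor of 3 reads over both libraries A_HT_DHD_18 with B_HT_DHD_18 was at least 5.06-fold lower, B_HT_DHD_41 with A_HT_DHD_41 at least 4.60-fold and A_HT_DHD_41 with B_HT_DHD_41 at least 4.48-fold, and with these pairs at their bounds the median of intended pairs stayed at 0.53. B_HT_DHD_33 with A_HT_DHD_33 was at -4.66 ± 2.09 and B_HT_DHD_30 with A_HT_DHD_30 at -4.13 ± 1.66, from 1 and 2 reads after selection over both replicates, not past the threshold. The highest medians over partners were 2.78 for mALb8_cutT1_B, 2.52 for B_HT_DHD_45 and 2.12 for B_ZCON_154 as row proteins, and 3.02 for B_HT_DHD_13, 2.46 for A_HT_DHD_64 and 2.45 for B_HT_DHD_81 as column proteins. These medians came mostly from replicate 2, as for A_HT_DHD_64 (0.09 in replicate 1 and 3.14 in replicate 2). Both orientations correlated with r = 0.314 (Spearman rho 0.233) over 53331 unordered pairs and r = 0.693 (rho 0.615) over 160 intended ones; rho over all pairs was 0.135 in replicate 1 alone.

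The Bcl pool set designed inhibitors against the pro-survival homologues of the Bcl-2 family. The 4 inhibitors named for a homologue (alphaBCL2, alphaBCLB, alphaBFL1 and alphaMCL1) had their highest value, as the mean of both orientations, with that homologue in both replicates. Single orientations could differ. In replicate 2 alphaBFL1 as row protein was at 3.75 with Bcl-xL and 3.43 with Bfl-1. There alphaBCL2 as column protein was at 2.05 with Bcl-w and 1.59 with Bcl-2. Averaged over orientations alphaBCLB was at 3.99 with Bcl-B and at -0.06 with the next homologue, Bfl-1. alphaMCL1 was at 3.52 with its target and at 1.43 with Bfl-1, alphaBCL2 at 3.01 with Bcl-2 and at 2.11 with Bcl-xL, and alphaBFL1 at 4.05 with Bfl-1 and at 3.67 with Bcl-xL. BCDP01 was above 0 in both replicates with 6 of 6 homologues and XCDP07 with 5 of 6, with highest values of 4.35 for BCDP01 with Bcl-B and 4.16 for XCDP07 with Bcl-w. For the other inhibitors the highest homologue differed between replicates or from the average. 2CDP06 was at 2.62 with Bcl-w (-0.26 and 2.97 in replicates 1 and 2) and at 2.53 with Bcl-2 (2.46 and 2.41), BECM01 at 3.91 with Bcl-B (4.07 and 1.97) and 3.32 with Bfl-1 (2.86 and 3.71), and FECM04 at 3.78 with Bcl-xL (2.07 and 4.04) and 3.72 with Bfl-1 (3.06 and 4.20). BCDP01 was highest with Bcl-B in replicate 1 and Bfl-1 in replicate 2, and XCDP07 with Bcl-B and Bcl-w.

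As a class the 108 inhibitor and homologue pairs had a median of 1.28, against -1.09 for 72 pairs of inhibitors and -0.48 for 30 pairs of homologues. By replicate these medians were 0.66 and 0.78, -1.15 and -1.39, and 0.20 and -1.12, so homologue pairs had opposite signs. The 8 intended pairs, all above 0 in both replicates, had a median of 3.66 against -0.38 for other heterodimers, a difference of 4.04 (exact permutation p = 0.0833, the smallest that 24 arrangements allow). Their single values reached from 2.45 ± 1.30 for Bcl-2 with alphaBCL2 to 4.41 ± 1.36 for Bfl-1 with alphaBFL1. In edgeR's test, which left out the pairing by library set, 0 of 225 pairs were enriched and 0 depleted (21 higher and 9 lower at an unadjusted p under 0.05). Adjusted over the list alone 0 of 8 intended pairs were enriched, whereas DESeq2 gave 39 enriched and 13 depleted. Reads before selection correlated between the library sets with a Spearman rho of -0.033. The spread in that fit therefore includes differences between the library sets, and its 0 calls do not show that pairs were unchanged. With replicate as a block 24 pairs were enriched and 20 depleted, among them alphaMCL1 with its target in both orientations (3.64 and 3.41) and alphaBFL1 with Bfl-1 (3.64), and without the replicate 2 library after selection 8 were enriched. Both orientations correlated with r = 0.897 (Spearman rho 0.813) over 105 unordered pairs, which are not independent. XCDP07, Bcl-2 and BCDP01 had the highest medians over partners as row proteins (0.85, 0.84 and 0.51), and BCDP01, Bcl-B and Bcl-xL as column proteins (0.90, 0.48 and 0.42).

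**Figure D5:**
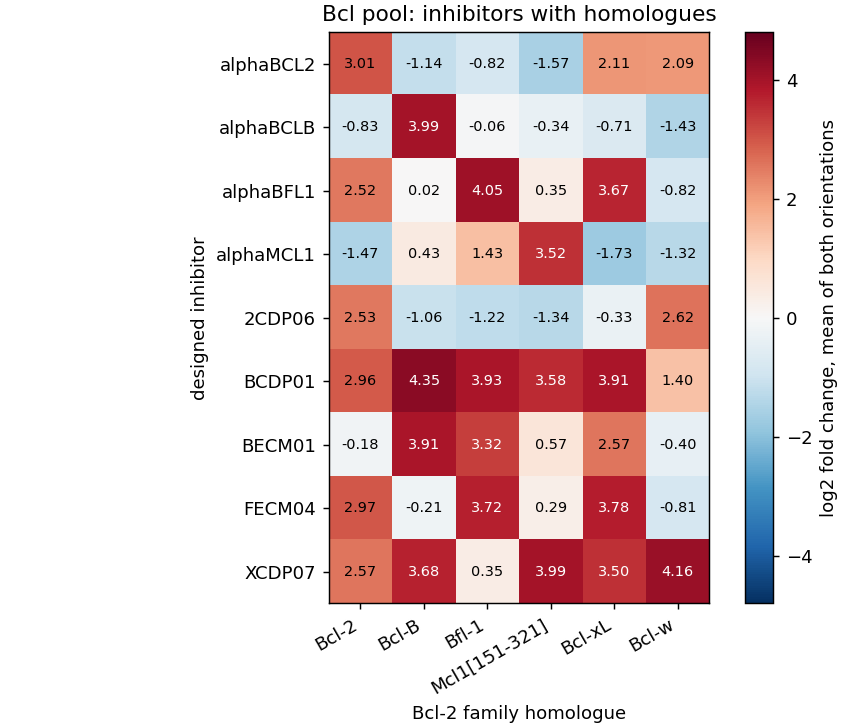
Log2 change after over before selection of designed inhibitors (rows) with Bcl-2 family homologues (columns) in the Bcl pool, from the fit to 2 replicates and averaged over both orientations. The 4 inhibitors named for a homologue are highest in that homologue's column, at 3.01, 3.99, 4.05 and 3.52.

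The 4 pools with 1 library per condition have no replicate check and no test of single pairs. Intended pairs exceeded other heterodimers by a median log2 ratio of 1.00 in the DHD subset (99 pairs; interval 0.92 to 1.08), 7.55 in the pool of NICP and mALb T designs (34 pairs; 7.43 to 7.58), 8.39 in the pool of AnBn, NICP, N and PA peptides (39 pairs; 8.31 to 8.45) and 0.67 in the mALb R pool (81 pairs; 0.60 to 0.79). Each median lay above those of 10000 random pairings, at the 99.99th percentile. Series differed within pools. In the AnBn pool the 18 AnBn pairs had a median of 1.46 above other pairs, and Jerala_P, N and PA pairs 9.02, 9.19 and 9.30. In the mALb R pool 7 Jerala_P pairs had a median of 7.62 and 74 mALb R pairs 0.46. Across shared intended pairs, which are not independent, Spearman rho with the replicated pools was 0.733 for the DHD pool and its subset, 0.838 for the Coiled pool and the NICP and mALb T pool, 0.759 for the Coiled pool and the AnBn pool, and 0.75 for the Coiled pool and the mALb R pool. Over all shared pairs these values were 0.309, 0.379, 0.344 and 0.404. They were lower over the few intended pairs shared by other pools: 0.429 for the DHD pool and the NICP and mALb T pool (6 pairs), and, for the NCIP pool at 2 mM and 10 mM, 0.385 and 0.315 with the NICP and mALb T pool (12 pairs), 0.418 and 0.436 with the AnBn pool (11 pairs) and -0.429 at either concentration with the mALb R pool (7 pairs). Between replicated pools rho over intended pairs was 0.19 for the DHD and Bcl pools (8 pairs). With the Coiled pool it was 0.364 and 0.308 for the NCIP pool at 2 mM and 10 mM (12 pairs). AN4 with BN4 stood at 8.51 above other pairs and AN3 with BN3 at -0.45 in the AnBn pool.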

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

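No test was made of the differences in this part; all values were read off after the data were seen, except that the mislabelling test was set before its values. Bcl-2 with alphaBCL2 went opposite ways in 2 pools: it lay at -1.82 in the DHD pool (-0.90 in replicate 1; from 51 reads to 0 in replicate 2, which bounds the value only) and at 2.45 in the Bcl pool (3.35 and 1.59), a difference of -4.27 that was not tested. With the fusions swapped, alphaBCL2 with Bcl-2 lay at 6.09 in the DHD pool, which rests on replicate 1 (7.41, with 38 reads to 0 in replicate 2). In the Bcl pool it lay at 3.57 (2.17 and 3.84 in replicates 1 and 2). It was raised because each replicate of one pool was below 0 and each of the other above, which held for 1 of 37 intended pairs compared.

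The libraries without a group were raised because they hold signal outside every comparison. The top 1% of pairs held 6.878% and 57.991% of reads in the libraries of replicate 1 and 19.310% and 7.025% in those of replicate 2. Their titles and descriptions give opposite selection states. With the titles taken as they stand, the log2 ratio correlated with the DHD subset at 0.288 in one pair of libraries and at -0.264 in the other, which could mean that 1 pair of libraries carries swapped states. Intended minus other pairs was 0.71 and -0.55 on the same basis, and intended pairs held 0.42% and 3.24% of reads in the libraries titled before and after selection of replicate 1 and 1.43% and 0.42% in those of replicate 2. The sample sheet alone cannot tell which of title and description is right.

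Bcl-w-trunc, a protein present in the Bcl library set of replicate 2 only, was raised because it enters no comparison, and reached 5.59 above other pairs as column protein with the inhibitor XCDP07, where Bcl-w in the same libraries stood at 5.73 (5.09 in the other orientation).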

How the results depend on the processing

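The intended pairs stayed above other heterodimers in every replicated pool under every alternative, by 0.42 to 2.22 in the DHD pool, 3.38 to 4.21 in the Bcl pool, 7.73 to 9.94 and 5.86 to 6.62 in the NCIP pool at 2 mM and 10 mM, and 2.87 to 3.98 in the Coiled pool. The 2.22 came with the filter at 50 reads, which also counts reads after selection and so favours pairs that rose. Counts of calls depended on the processing. DESeq2 gave 7961 enriched (105 intended) and 115 depleted in the DHD pool, 39 and 13 in the Bcl pool, 21 and 17 enriched in the NCIP pool at 2 mM and 10 mM with 2 changed between them, and 2004 enriched (65 intended) and 348 depleted in the Coiled pool; the cause was not tested. Library size in place of TMM gave 92 and 97 depleted in the NCIP pool at 2 mM and 10 mM, and 507 enriched (52 intended) and 8646 depleted in the Coiled pool. It moved the bulk of pairs below 0 and by that turned Jerala_P7 with Jerala_P8 to -0.50 and Jerala_P6 with Jerala_P5 to -0.11 at 2 mM, and to -4.04 and -2.39 at 10 mM, where Jerala_P11 with Jerala_P12 went to -2.13. With replicate as a block the Bcl pool had 24 enriched and 20 depleted, and the NCIP pool at 10 mM and the Coiled pool 2 depleted each; the block changed no other count of calls by over 1.5 times, and no call of a named pair outside the Bcl pool. In the Coiled pool 1 pair was depleted without a filter and 1 with a filter at 50 reads; the cause was not tested. The orientation correlation was 0.135 for replicate 1 alone in the DHD pool and 0.161 for replicate 2 alone in the Coiled pool, and the DHD subset difference 0.91 with a pseudocount of 5; the cause was not tested. With each library left out, where the lone library is taken to vary like the other group, calls ranged from 0 to 8347 enriched, 0 to 2063 depleted and 0 to 110 intended in the DHD pool, 0 to 8 enriched in the Bcl pool, 0 to 13 and 0 to 6 in the NCIP pool at 2 mM and 10 mM, and 2 to 3915 enriched, 0 to 3270 depleted and 1 to 72 intended in the Coiled pool; the cause was not tested. Over named pairs and all alternatives 445 values kept direction and side of the threshold, 60 lost the threshold, 32 passed it and 5 reversed. At the depth and common dispersion of the DHD pool the fit recovered 2% of simulated pairs changed by a log2 of 4 and 75% of those changed by 8. Depth alone was not tested as the limit, and a filter at 50 reads left 0 calls. No alternative by barcode was run, since each protein has 1 barcode.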

Other observations

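The lists of this part were made after the values were seen, as were the tests of binding and of growth from N1 alone; the other tests were set before. Peptides of different series paired by number in the Coiled pool. Across the Jerala_P, PA and N series 28 pairs that joined the numbers of 1 designed pair had a median log2 change of 6.52, and 17 were enriched, such as P5A with N6 at 7.41 and P6A with Jerala_P5 at 7.39. The 232 pairs with other numbers had a median of 0.33 and 0 enriched. Low values stood between N and Jerala_P at the numbers 1 and 2: N2 with Jerala_P1 lay at -0.52, Jerala_P2 with N1 at -0.01, Jerala_P1 with N2 at 0.71, while N1 with Jerala_P2 lay at 3.61, against a median of N1 over all partners of 5.35, and in the AnBn pool at 8.47, against 8.04. N7 with Jerala_P8 lay at -0.32. In the AnBn pool the medians were 8.43 and 0.34.

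Forms of 1 design, whose suffixes were not explained in the sources used here, had values from low to high. In the DHD pool mALb8 averaged 8.14 over both orientations and mALb8_cutT1 8.08, but mALb8_cutT2 -0.93 and mALb8_cutT4 -0.78, where few reads were left after selection in replicate 2. ZCON_VR_2 was at 7.48, its cutT2 form at 7.51 and its cutT4 form at -1.26. Forms in between and above 0 in both replicates were ZCON_155_LL at 4.72 (5.84 and 2.95) and ZCON_15_re_loop at 2.60 (1.76 and 2.81), among others. These averages come from fits with 0 pairs past the threshold. Homodimers had fewer reads than heterodimers before selection, with medians of 21 against 2902.5 in the NCIP pool and 97 against 228 in the DHD pool (replicate 1).

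N1 as row protein grew with most partners, at a median of 5.35 in the Coiled pool and 8.04 in the AnBn pool. Few reads could not account for this, with 430 median reads before selection in the lower replicate. Growth from the N1 fusion alone stays open: 94.6% of partners were above 0 in both replicates of the Coiled pool, all but 7, which were Bcl-2 family proteins or inhibitors with few reads, and this restates the pattern without testing its source. Binding of most partners stays open as well. With N1 as column protein the median was -0.07 in the Coiled pool, with 27 of 122 partners above 0. In the AnBn pool it was 0.72, with 34 of 37 partners above 0.

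Over all tested pairs, log2 ratios of the large pools correlated weakly between biological replicates. Spearman rho was 0.216 in the DHD pool and 0.398 in the Coiled pool. Over intended pairs alone rho was 0.5 in the DHD pool (325 pairs) and 0.866 in the Coiled pool (113 pairs), so the weak value does not describe intended Coiled pairs. In the DHD pool the fewer reads of replicate 2 could not by themselves account for the weak value. Replicate 1 thinned to that depth correlated with itself at 0.804. Thinned reads come from the same cells and PCR products, so this test does not cover a loss of cells or templates before sequencing. In the Coiled pool sequencing runs could not account for the weak value, since technical runs correlated at 0.912 or more. Biological replicates there correlated run by run at 0.376 or less. The DHD pool had no technical runs, so sequencing runs were not tested there. Counting error before selection could not account for the weak DHD value. Over 6038 DHD pairs with at least 100 reads in each library before selection the correlation was 0.202. Reads after selection were not filtered, so this test does not exclude counting error there. What differs between the cultures was not tested.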
